A study of Mus musculus with 10 samples.

How the data were processed

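Gene expression was measured on 10 Affymetrix arrays, each hybridised with biotin-labelled RNA from medullary thymic epithelial cells (mTECs) of mice aged 3 weeks on a C57BL/6 background. The cells had been sorted, per the labels, as negative for the leukocyte marker CD45, positive for the epithelial marker EpCAM and high for CD80, a costimulatory molecule of mature mTECs. The labels put 5 arrays in a wild-type (WT) group and 5 in a group lacking the transcription factor Fezf2 (KO). Arrays are named here by their title numbers, WT 1 to WT 5 and KO 6 to KO 10. The labels do not say that the arrays came from separate mice, so the p-values measure only the spread between these arrays, which may be partly technical. No array duplicated another, since the highest correlation between any pair was 0.996.

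The deposited values are linear signal intensity per probe set, and MAS5, without a version, is the only tool named in the submitters' processing notes. The method behind the intensities stays uncertain. No deposited value was below 5.49, the array medians lay between 36.5 and 38.0, and the 2% trimmed means lay between 170.3 and 174.2 without being equal, whereas plain MAS5 scaling sets a common trimmed mean. The scaling target, the background step and any filter are not given in the sources used here. Detection calls were not used here, so no probe set could be called absent. For arrays, the number of arrays limits the precision.

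The table held 45101 probe sets. The platform annotation gave exactly 1 gene symbol for 34958 of them, several for 932 and none for 9211, and 34754 of the 34958 were matched by Entrez gene identifier to a RefSeq gene table of assembly GRCm38.p6, which was used for names and for the order of neighbouring genes. Since no genome build is named for the arrays, no coordinates are given. Probe sets were kept where the signal exceeded the 40th percentile of its own array on at least 5 of the 10 arrays, which left 23581 probe sets with 1 gene. Each gene was then represented by the kept probe set with the highest mean, which gave 14086 genes tested.

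Signals were analysed as log2(value + 16) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend and robust estimation), without further normalization, as KO minus WT. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. Every fold change is on the log2(value + 16) scale, which understates the change of genes with low signal. Group levels are means of the deposited signals ± SD over 5 arrays. Fezf2 and Aire were also compared by an exact two-sided permutation test. The limma procedure was tested on simulated arrays with the 14086 genes and the spread of this comparison. It recovered 72% of 100 genes given a log2 change of 0.5 and 96% of 100 genes given a log2 change of 1, with 12 false calls, and it made 0 calls when no gene was changed. The genes were simulated independently of each other, without effects shared across an array. These figures therefore do not give the error rate on the real arrays.

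There were 30 gene lists, written before the data were examined, with 508 different genes, of which 412 were measured. They covered Fezf2-linked, Aire-dependent and Aire-independent antigens, mature and immature mTECs, thymic epithelium, cortical epithelium, cornified cells, tuft cells, microfold cells, enterocytes and hepatocytes, liver products, neuroendocrine cells, ciliated cells, muscle, ionocytes, pancreas, the male reproductive tract, brain and eye, milk proteins, proliferation, interferon-stimulated genes, dissociation stress, thymocytes, myeloid cells, B cells, fibroblasts, endothelium, erythroid cells and sex-linked transcripts. A gene could stand in several lists. The sex-linked list had 1 kept member, Xist, and was not tested as a list. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists. The genes named in the text followed a rule set before the data were examined. It took Fezf2 and Aire, the 12 genes with the largest fall and the 12 with the largest rise among those past the threshold whose KO and WT values did not overlap, leaving out unnamed predicted genes, and up to 4 members past the threshold with the smallest adjusted p from each list. List members outside that rule are named where they complete a description, and were then chosen after their values were seen.

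The alternatives were offsets of 1 and 64, quantile normalization, median centring, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, probe sets without the suffixes of shared sequence, eBayes without trend, array weights, an adjusted p threshold of 0.01 and each array left out in turn. Further alternatives were added after the data were seen, namely arrays WT 1 and KO 6 as a block or left out, the poly-A spike-in level as a covariate, and the presence of Xist signal as a block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.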

Results

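The data were signals of 14086 genes in sorted CD80-high mTECs from 5 WT and 5 Fezf2 KO arrays. These cells line the thymic medulla and express proteins of many peripheral organs, to which developing T cells are exposed. Fezf2 is a zinc finger transcription factor, and the comparison asks which genes of these cells depend on it. Correlations of log2 signals lay between 0.981 and 0.995 among WT arrays, between 0.977 and 0.996 among KO arrays, and between 0.951 and 0.974 across genotypes. The first principal component held 55.4% of the variance and separated the genotypes, and the second held 16%. WT 1 and KO 6 had the highest poly-A spike-in signals, 583 and 824 against 125 to 455 on the other arrays, and the highest 18S rRNA signals, 3445 and 3762 against 765 to 1774. Xist, transcribed from the inactive X chromosome of females, was between 21.1 and 30.0 on WT 2, KO 6 and KO 8 and between 5304 and 6100 on the other arrays, so that arrays without Xist signal numbered 1 of 5 in WT and 2 of 5 in KO.

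Fezf2 itself was 5475 ± 350 in WT and 15.04 ± 2.77 in KO cells (SD, n = 5 each). Its KO signals, 12.1 to 18.3, lay below the 40th percentile of each array, and the fall was at least 145-fold when that percentile was taken as the floor. The fitted log2 change was -7.47 (SE 0.07, adjusted p = 5.2e-15), and the exact two-sided permutation test gave p = 0.00794, the smallest value possible with 5 against 5 arrays. Which part of the gene was deleted is not given in the labels.

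Fezf2 KO cells had lost much of the signal of several genes normally typical of other organs, and had gained signal of a mixed set of genes. After Fezf2, the largest falls were of Krt10, a keratin of the suprabasal epidermis, from 2635 ± 607 to 455 ± 47.1 (5.55-fold), and Ttr, the thyroid hormone carrier transthyretin, from 1204 ± 214 to 210 ± 26.1 (5.35-fold). Resp18, a protein of neuroendocrine secretory granules, fell from 1302 ± 361 to 229 ± 17.3 (5.24-fold), and the kallikrein Klk1b16 from 862 ± 139 to 174 ± 56.6 (4.77-fold). The other genes in this group were Apoc3, Fabp9, Smtnl1, Maoa, Calb1, Cracd and Nol4, with log2 changes from -2.22 for Apoc3 to -1.85 for Nol4. Weaker probe sets of Maoa and Nol4 gave -0.83 and -0.53, and the 4 probe sets of Ttr gave -2.42 to -1.68. Mpeg1, the macrophage pore-forming protein perforin-2, rose from 67.9 ± 8.04 to 502 ± 67.7 (6.16-fold), and Scel, the cornified envelope protein sciellin, from 217 ± 38.02 to 1423 ± 244 (6.15-fold). Wfdc12, a protease inhibitor of the whey acidic protein family, rose from 187 ± 20.1 to 1173 ± 329 (5.73-fold), Msln, the cell surface protein mesothelin, from 839 ± 46.7 to 4401 ± 128 (5.17-fold), and Btla, an inhibitory receptor of lymphocytes, from 79.6 ± 10.3 to 466 ± 57.1 (5.03-fold). Fetub, Gsto1, Pxylp1, the cytokine gene Il18, Wfdc15b, Arg1 and the claudin gene Cldn8 followed, with log2 changes from 2.27 for Fetub to 2.05 for Cldn8. The adjusted p was at most 1.3e-04 for each of these genes, the highest being that of Fabp9, and none of their KO values overlapped the WT values.

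**Figure D1:**
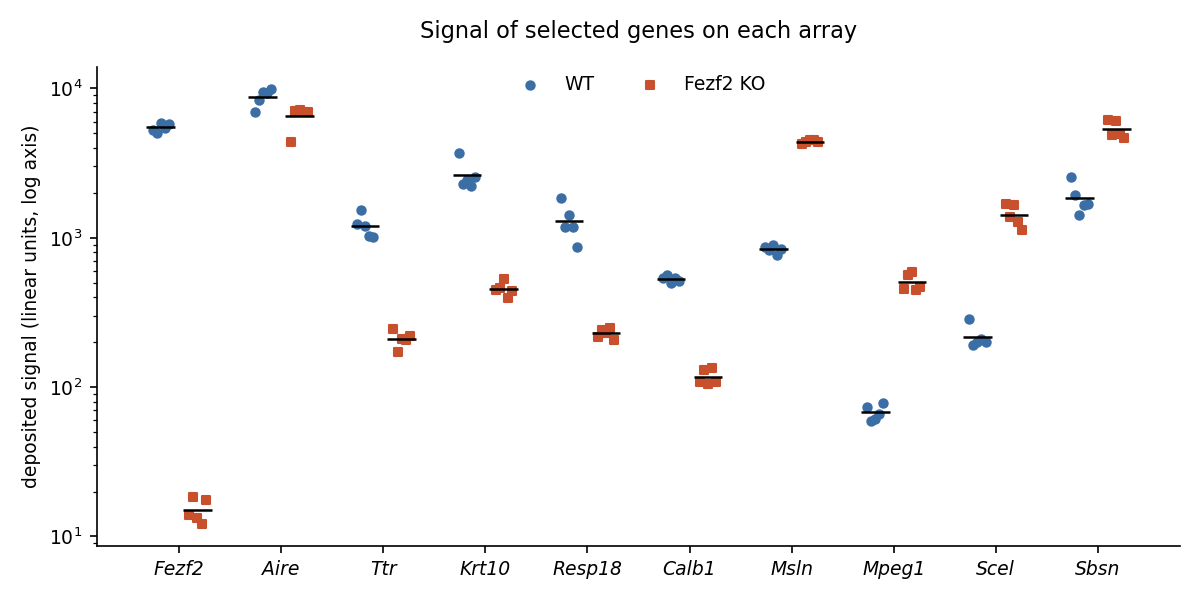
Deposited signal (linear units on a log axis) of 10 genes on each array, with WT as circles, Fezf2 KO as squares and group means as bars. The 5 KO signals of Fezf2 sit between 12.1 and 18.3, the WT signals between 5054 and 5895, and only for Aire do the groups overlap.

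Over all genes, 2278 were lower and 1835 higher in KO cells (limma, adjusted p under 0.05), together 29.2% of those tested. Changes of at least 2-fold were found for 142 lower and 167 higher genes. The KO values lay entirely below the WT values for 1692 genes (12%) and entirely above them for 1421 (10.1%), against 0.794% expected by chance in both directions together. The median log2 change of all genes was -0.03. Without WT 1 and KO 6, 4415 genes were called, of which 3722 were among the 4113 called with all arrays, every one in the same direction.

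**Figure D2:**
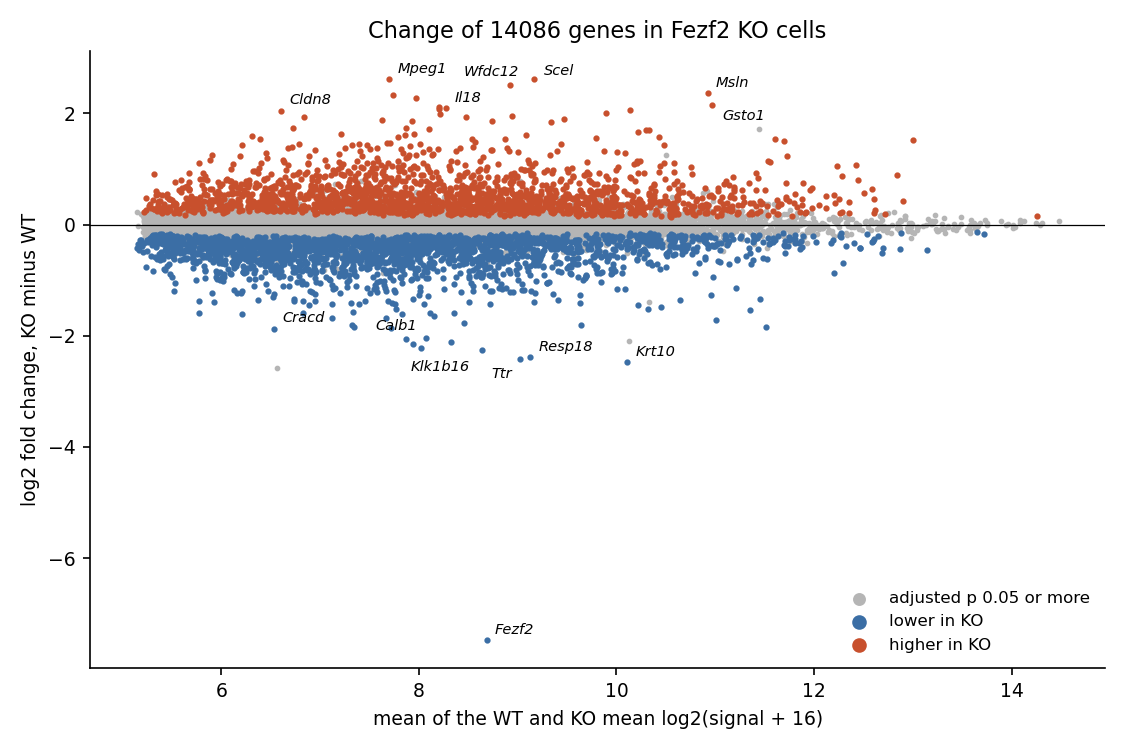
Log2 fold change (KO minus WT) of each of 14086 genes against the mean of the group mean log2(signal + 16) values, with 2278 lower genes in blue, 1835 higher genes in orange and the rest in grey. Fezf2 stands apart at -7.47, and the next lowest gene past the threshold is Krt10 at -2.47.

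Genes recalled as Fezf2-linked antigens fell as a group. Of 16 members, 13 were lower, 1 was higher and 2 were not past the threshold (14 lower and 1 higher adjusted over the list alone), with a median log2 change of -1.72 (camera, adjusted p = 1.4e-10, and adjusted p = 0.22 with an estimated correlation). This list was drawn from memory of work that used these samples, so it is not independent evidence of its direction. Krt10, Ttr, Maoa and Calb1, the calcium-binding protein calbindin, were among the members that fell, Calb1 from 529 ± 26.6 to 117 ± 14.1. Sbsn, the epidermal protein suprabasin, went the other way, from 1856 ± 435 to 5325 ± 697, and Itih3 and Tff3 had log2 changes of -0.57 and 0.19. Fry, which asks only whether the members of a list move on balance one way and does not compare them with other genes, gave an adjusted p of 4.1e-06.

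Aire, the other known regulator of peripheral antigens in these cells, was modestly lower, 6504 ± 1199 in KO against 8791 ± 1156 in WT cells (log2 change -0.45, SE 0.14, adjusted p = 0.0282). The groups overlapped, and the exact two-sided permutation test gave p = 0.0317. The lowest KO signal, 4368, was on KO 6 and the lowest WT signal, 6966, on WT 1. The change was -0.31 (adjusted p = 0.0185) without KO 6 and -0.53 without WT 1. The call was lost without WT 3 (-0.42, adjusted p = 0.0613), WT 4 (-0.42, adjusted p = 0.0640) or WT 5 (-0.40, adjusted p = 0.0680).

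Aire-dependent antigens were divided. Of 19 members, 8 were lower, 1 was higher and 10 were not past the threshold (9 lower and 3 higher adjusted over the list alone), with a median of -0.27 (camera, adjusted p = 0.0154, and adjusted p = 0.50 with an estimated correlation). The members that fell included Fabp2, the intestinal fatty acid binding protein, from 492 ± 100 to 146 ± 17.4, Sult1c2 with a log2 change of -1.27, the fibrinogen gene Fgb with -1.15 and the odorant-binding protein gene Obp1a with -0.75. S100a8 rose by 0.57, and the seminal vesicle genes Svs2 and Svs5 had changes of 0.30 and 0.24. The call was lost without WT 1 (median -0.15, 7 lower and 3 higher, adjusted p = 0.0887), and the median was -0.14 without WT 2 (adjusted p = 0.0431). Of 7 Aire-independent antigens 1 was lower, Cyp1a2, and none passed adjusted over the list alone (median -0.18, camera, adjusted p = 0.68). The call of Cyp1a2 was lost in 5 of the 10 fits that left out 1 array.

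The markers of mature mTECs did not shift as a group, with 6 of 23 lower, 2 higher and 15 not past the threshold, also adjusted over the list alone, and a median of -0.03 (camera, adjusted p = 0.81). Within the list, Fas, a death receptor, fell from 902 ± 93.7 to 433 ± 68.9, Ciita, the transactivator of MHC class II genes, from 482 ± 39.7 to 271 ± 45.4, and the chemokine gene Ccl17 from 338 ± 69.7 to 203 ± 44.1. Tnfrsf11a, the receptor RANK, rose from 425 ± 28.2 to 733 ± 35.2. Cd80, part of the gate, had a log2 change of -0.17 (adjusted p = 0.32), and the class II gene H2-Aa had one of 0.06 (adjusted p = 0.15).

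The lists of enterocytes and hepatocytes, liver products and pancreas were lower in KO cells. Of 24 measured enterocyte and hepatocyte genes 22 were lower, none was higher and 2, Reg3g and Cdx2, were not past the threshold, also adjusted over the list alone, with a median of -1.01 (camera, adjusted p = 4.7e-14, and adjusted p = 0.22 with an estimated correlation). Saa3, an acute-phase apolipoprotein, fell from 5554 ± 655 to 1541 ± 209, Apoa4 from 2345 ± 365 to 833 ± 129, and Vil1, the microvillus protein villin, had a log2 change of -1.43. Hnf4a and Hnf4g, transcription factors of intestine and liver, had changes of -0.78 and -0.33, both past the threshold. Ttr, Apoc3 and Apoa4 also stand in the Fezf2-linked list and Fabp2 and Reg3g in the Aire-dependent one. Of 23 genes of liver products 13 were lower and 2 higher (14 lower and 2 higher adjusted over the list alone), with a median of -0.59 (camera, adjusted p = 8.0e-04, and adjusted p = 0.36 with an estimated correlation). Fga had a log2 change of -0.96 and Apoa2 one of -0.55, while Cps1, the first enzyme of the urea cycle, rose by 0.53. Of 11 endocrine and exocrine pancreatic genes 8 were lower and 1, Iapp, was higher, also adjusted over the list alone, with a median of -0.54 (camera, adjusted p = 0.0019, and adjusted p = 0.36 with an estimated correlation). Cela3b, an elastase, fell from 489 ± 55.7 to 250.0 ± 34.7, and Ctrb1, Cela2a and the glucagon gene Gcg had changes of -0.60, -0.84 and -0.71.

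Other lists of peripheral tissues held genes that fell, while the lists did not pass in camera, which compares them with all other genes. Fry gave an adjusted p of 2.7e-04 for each of the neuroendocrine, brain and eye, and milk protein lists and of 0.0381 for muscle, all downward. Of 23 neuroendocrine genes 9 were lower and 2 higher (10 lower and 2 higher adjusted over the list alone; median -0.25, camera, adjusted p = 0.061). Car8 fell from 273 ± 93.6 to 78.1 ± 5.74 and the neurotensin gene Nts from 2770 ± 166 to 1450 ± 220, while the transcription factor gene Neurod1 rose by 0.76. That list passed without WT 3 (adjusted p = 0.024) or KO 8 (adjusted p = 0.0384). It also passed without a filter (adjusted p = 0.0248) and with a filter at the 60th percentile (adjusted p = 0.0111). Of 15 genes of brain and eye 5 were lower and 1 higher (8 lower and 2 higher adjusted over the list alone; median -0.21, adjusted p = 0.061), with a change of -1.07 for Calb2 and 0.88 for Cryab, and this list too passed without WT 3 (adjusted p = 0.0395) or KO 8 (adjusted p = 0.0384) and with a filter at the 60th percentile (adjusted p = 0.0454). Of 6 milk protein genes Csn1s1, Wap and Csn1s2a were lower, also adjusted over the list alone (median -0.25, adjusted p = 0.082). Among 11 genes of the male reproductive tract 3 were lower, also adjusted over the list alone, with Fabp9 from 558 ± 294 to 101 ± 6.49 (median 0.005, mean -0.15, adjusted p = 0.99). That median was 0.07 without WT 1 and -0.05 without KO 6, and 1 of the 3, Acrv1, lost its call in 7 of the 10 fits that left out 1 array. Of 19 muscle genes 6 were lower and 2 higher (7 lower and 2 higher adjusted over the list alone; median -0.13, adjusted p = 0.20), with Myh3, embryonic myosin, falling from 207 to 96.5 and Myl1 rising by 1.29. Of 18 ciliated cell genes Dnah9 and Fam183b were lower, also adjusted over the list alone (median -0.09, adjusted p = 0.30). The ciliated cell median was -0.002 without KO 6, whose mean log2 signal of 6.38 lay below the 6.83 to 6.91 of the other KO arrays. Of 7 ionocyte genes the chloride channel gene Cftr was higher, with a change of 0.94, and Foxi1 lower with -0.51, also adjusted over the list alone (median 0.05, adjusted p = 0.30). The ionocyte median was 0.01 without KO 6, 0.02 without WT 1 and -0.03 without both, and the call of Foxi1 was lost in 4 of the 10 fits that left out 1 array.

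Tuft cell genes, of a chemosensory epithelial cell type, were lower in 5 of 22 cases and higher in 1, also adjusted over the list alone, with a median of -0.33 (camera, adjusted p = 0.063; fry, adjusted p = 0.171). The list passed with WT 1 and KO 6 as a block (adjusted p = 0.0191, 10 lower), without both (adjusted p = 0.048) and with the Xist block (adjusted p = 0.0312). It also passed with array weights (adjusted p = 0.0395), without a filter (adjusted p = 0.0478) and with the mean of probe sets (adjusted p = 0.0426). Il17rb and Sh2d6 fell by 0.59 and 0.73 on the log2 scale, and L1cam rose by 0.76. KO 6 stood above the other KO arrays in this list, with a mean log2 signal of 7.97 against 7.44 to 7.55, and WT 3 was the lowest of all arrays with 7.41. Without KO 6, 12 members were lower and the list passed (median -0.44, adjusted p = 0.00739), as it did without WT 3 (median -0.43, adjusted p = 0.00338). Without WT 1, 3 members were lower and the median was -0.25 (adjusted p = 0.345).

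Cornified cell genes rose as a group while a pair of early epidermal keratins fell. Of 21 members 10 were higher, 3 lower and 8 not past the threshold (11 higher and 3 lower adjusted over the list alone), with a median of 0.43 (camera, adjusted p = 0.0029, and adjusted p = 0.50 with an estimated correlation). Sprr1a, a cornified envelope precursor, rose from 1960 ± 291 to 5589 ± 488, Sbsn by 1.53 on the log2 scale, and Krt80 from 205 ± 15.2 to 446 ± 93.4. The members that fell were Krt10, its partner Krt1, from 323 ± 89.2 to 113 ± 19.3 (log2 change -1.37), and Krt77 (-0.24), whose call was lost in 7 of the 10 fits that left out 1 array.

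The lists of thymic epithelium and of the cortex were also higher in camera, though most of their members did not pass singly. Of 19 genes of thymic epithelium 8 were higher and 1 lower (8 higher and 3 lower adjusted over the list alone), with a median of 0.09 (camera, adjusted p = 0.0154, and adjusted p = 0.50 with an estimated correlation). This call was lost with array weights (adjusted p = 0.0775) and without WT 1 and KO 6 (median 0.05, adjusted p = 0.0646). Without KO 6 alone the median was also 0.05. The number of lower members was 3 without WT 1, 0 without KO 6 and 4 with WT 1 and KO 6 as a block. Pax9, a transcription factor of the pharyngeal pouches, rose from 156 ± 10.0 to 340 ± 15.1, with its 3 probe sets between 0.63 and 1.05, and Pax1, Cdh1 and Grhl2 had changes of 0.52, 0.42 and 0.38. Of 14 cortical epithelium genes 5 were higher and 1 lower, also adjusted over the list alone, with a median of 0.28 (camera, adjusted p = 0.0207, and adjusted p = 0.50 with an estimated correlation). The cathepsin gene Ctsl rose from 5458 ± 1049 to 9991 ± 566, the chemokine gene Ccl25 from 4946 ± 438 to 7687 ± 457 and Enpep from 506 ± 55.0 to 907 ± 75.4, while Psmb11 and Prss16, genes of the cortical peptide machinery, had changes of 0.33 and 0.49 that did not pass (adjusted p = 0.58 and 0.18). KO 6 had the lowest mean of the cortical list, 8.85, against 9.23 to 9.34 on the other KO arrays. The median of that list was 0.18 without WT 1 or without KO 9, and 0.40 without KO 6. Of 8 immature mTEC genes 3 were higher and 2 lower (3 and 3 adjusted over the list alone; camera, adjusted p = 0.99), with Col17a1 falling from 421 ± 50.3 to 148 ± 22.1 and Krt15 by 0.61. Without WT 1, 3 were lower and 2 higher, and of the higher members Tnfrsf11b and Dcn lost their calls in 5 and 3 of the 10 fits that left out 1 array. A weaker probe set of Tnfrsf11b gave 0.11, against 0.49 for the one tested. The list's median was 0.08, its mean -0.05 and the direction given by fry downward (adjusted p = 0.0272). Of 10 microfold cell genes 4 were higher and none lower (5 higher adjusted over the list alone; median 0.32, camera, adjusted p = 0.058), with the chemokine gene Ccl6 from 604 ± 220 to 1496 ± 306. That list passed without WT 1 (adjusted p = 0.0106), WT 2 (adjusted p = 0.0431), KO 9 (adjusted p = 0.049) or KO 10 (adjusted p = 0.0288). It also passed with WT 1 and KO 6 as a block (adjusted p = 0.0328) or left out (adjusted p = 0.00849). Further passes came with array weights (adjusted p = 0.0138), with the mean of probe sets (adjusted p = 0.0446) and without probe sets of shared sequence (adjusted p = 0.0118).

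**Figure D3:**
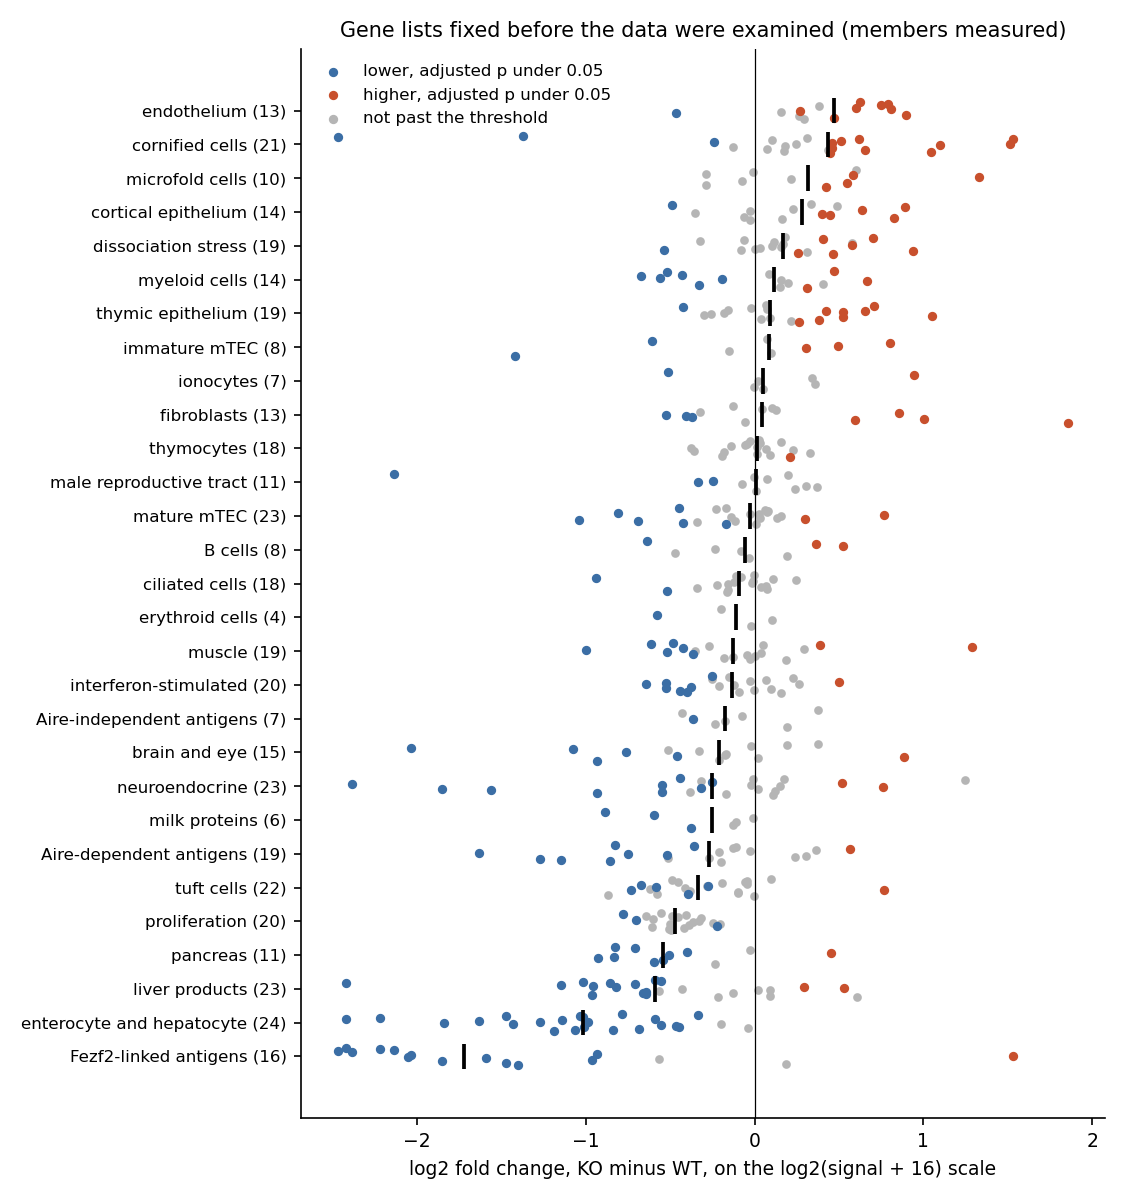
Log2 fold change (KO minus WT, log2(signal + 16) scale) of each measured member of 29 gene lists, with lower members in blue, higher ones in orange, those not past the threshold in grey and the list median as a black bar. The medians run from -1.72 for the Fezf2-linked antigens and -1.01 for enterocyte and hepatocyte genes to 0.47 for endothelium.

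Proliferation genes were lower as a list (20 members, median -0.47, camera, adjusted p = 0.0050, and adjusted p = 0.72 with an estimated correlation, 0.90 between members; fry, adjusted p = 0.142). Only 3 members, Top2a, Bub1b and Pcna, passed singly. None did adjusted over the list alone. Their calls were lost in 6, 4 and 8 of the 10 fits that left out 1 array. With WT 1 and KO 6 as a block 11 members were lower, with the poly-A spike-in covariate 12, and with the Xist block 1. KO 6 had the lowest mean log2 signal, 7.31, followed by KO 8 with 7.97, and these are the KO arrays without Xist signal. KO 7, KO 9 and KO 10 had 8.43, 8.50 and 8.53, close to the 8.45 to 8.82 in WT. Without KO 6, but with KO 8 still included, the median was -0.25 (camera, adjusted p = 0.0095). Genes induced by tissue dissociation were higher in 6 of 19 cases and lower in 1, also adjusted over the list alone, with a median of 0.17 (camera, adjusted p = 0.0206, and adjusted p = 0.72 with an estimated correlation; fry, adjusted p = 0.146). The immediate-early gene Nr4a1 rose from 590 ± 66.2 to 1154 ± 214, Fosb by 0.70 and Jun by 0.41. This call was lost without KO 6 (median 0.07, adjusted p = 0.102) or WT 3 (median 0.16, adjusted p = 0.0746), and without both WT 1 and KO 6 (median 0.08, adjusted p = 0.0646). Of 20 interferon-stimulated genes 7 were lower and 1 higher (7 lower and 2 higher adjusted over the list alone; median -0.14, adjusted p = 0.23), with Usp18 falling from 3324 ± 223 to 2153 ± 391 and Igtp by 0.53. The median of the interferon list was -0.04 without KO 6 and -0.06 with the Xist block, against -0.21 without KO 10.

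Markers of other cell types that a sort can carry along moved unevenly. Endothelial genes rose in 8 of 13 cases and fell in 1 (10 higher and 1 lower adjusted over the list alone; median 0.47, camera, adjusted p = 0.0010, and adjusted p = 0.48 with an estimated correlation), at low signals. Pecam1 rose from 23.0 ± 8.70 to 43.1 ± 4.25 and Emcn from 17.3 ± 6.88 to 34.0 ± 5.44. The mean log2 signal of the list was 6.22 to 6.76 in WT and 6.76 to 7.04 in KO. Flt1 fell from 131 ± 5.22 to 91.3 ± 16.4, while its weaker kept probe sets gave log2 changes of -0.29, -0.24 and 0.02. The rise of Egfl7 (0.81) was lost when probe sets of shared sequence were left out (0.38, adjusted p = 0.107). Of 13 fibroblast genes 4 were higher and 3 lower (4 and 4 adjusted over the list alone; median 0.04, -0.05 to 0.16 with 1 array left out, adjusted p = 0.35, and 0.0252 in fry, upward), with the peptidase gene Dpp4 from 113 ± 16.6 to 451 ± 60.6, Lum at 0.86 and Mfap5 at -0.37, while Col1a1 and Col3a1 had changes of -0.13 and 0.04. Of 14 myeloid genes 6 were lower and 3 higher (6 and 4 adjusted over the list alone; median 0.11, mean -0.02, adjusted p = 0.90), with Flt3, Csf1r and Lyz2 lower and C1qb higher. The myeloid median was 0.06 without WT 1. Of 8 B cell genes 1 was lower and 2 higher, also adjusted over the list alone (median -0.06, tested upward, adjusted p = 0.92), with Cd79b at -0.64, Ebf1 at 0.52 and Ms4a1 at 0.36. Without WT 1 or without KO 6, 2 B cell genes were lower, and without both 3 were. The B cell median was -0.02 without KO 6. Of 18 thymocyte genes 1, Zap70, was higher and none passed adjusted over the list alone (median 0.01, mean -0.01, adjusted p = 0.81). The call of Zap70 was lost in 3 of the 10 fits that left out 1 array. Its weaker kept probe sets gave 0.006 and -0.05, against 0.21 for the one tested. Without KO 6, 3 thymocyte genes were higher (median 0.06), and without WT 1 the median was -0.005. Of 4 erythroid genes 1, Epb42, was lower (2 adjusted over the list alone; median -0.11, adjusted p = 0.37, and 0.0252 in fry, downward). No list passed the threshold in camera with an estimated correlation, the smallest adjusted p being 0.22.

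**Figure D4:**
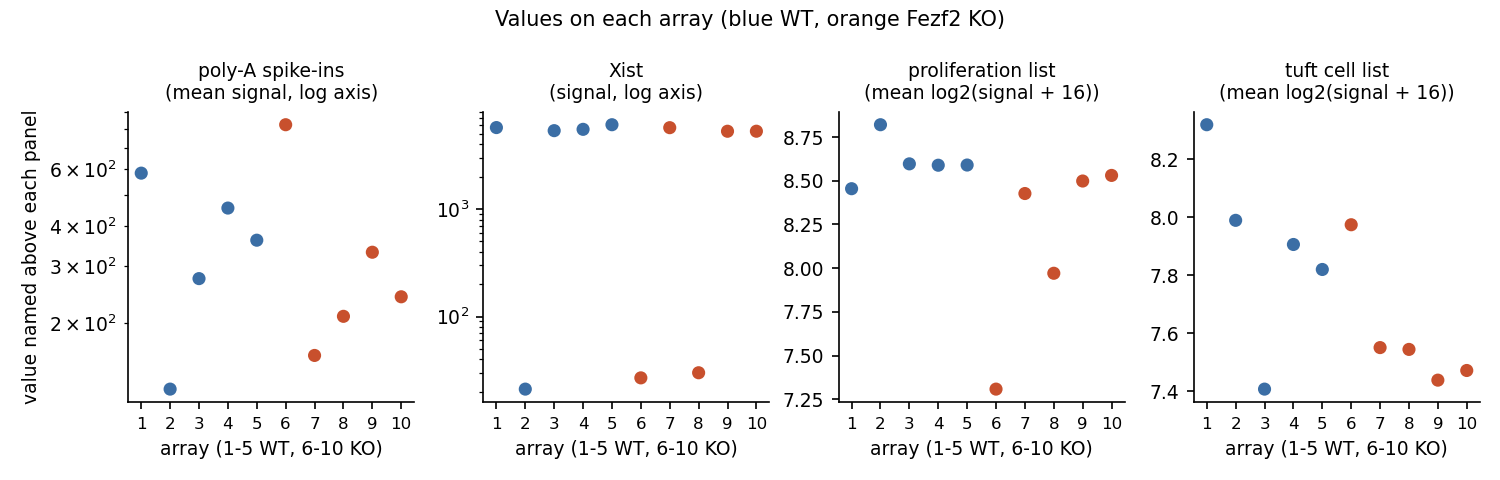
Mean poly-A spike-in signal and Xist signal (both on log axes), and mean log2(signal + 16) of the proliferation and tuft cell lists, on each array (WT 1 to 5 in blue, KO 6 to 10 in orange). KO 6 has the highest spike-in signal, 824, a Xist signal of 26.9 and the lowest proliferation mean, 7.31.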

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

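The tests on array KO 6 were chosen after that array had drawn attention, but before the values they measure were seen.

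In the gene lists and array measures, 9 of 70 groups of 5 arrays held a value whose gap to its nearest neighbour, divided by the range of the group, exceeded Dixon's critical value of 0.71, and among the named genes 12 of 218 groups did. Chance gives about 1 in 20. On KO 6 the mean log2 signal was 8.85 for the cortical epithelium list, 7.97 for the tuft cell list, 6.38 for the ciliated cell list, against 6.83 to 6.91 on the other KO arrays, and 7.22 for the muscle list, against 6.86 to 6.96. On the same array the log2 signal of Aire was 12.10, against 12.76 to 12.82, that of 18S rRNA 11.88, against 9.58 to 10.17, and those of Fas, Dcn and Igtp 8.38, 10.65 and 10.24. WT 1 stood apart in the 3' Gapdh control with 12.59, against 13.06 to 13.15, and in Krt10 with 11.86, Scel with 8.23, Btla with 6.83 and Pecam1 with 5.76. The liver product list was 7.26 on WT 3 and the endothelial list 7.04 on KO 8, against 6.76 to 6.83 on the other KO arrays. Single genes apart on other arrays were Enpep on WT 5 (9.27), Ccl25 on WT 3 (12.03), Lyz2 on KO 10 (11.37), Cd79b on KO 9 (7.12) and Xist on WT 2 (5.21).

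The low proliferation signal of KO 6 may come from the state of its RNA, from the mouse or from the cells sorted. WT 1 shares the high spike-in and 18S signals, and its proliferation mean was -0.13 from the lowest of the other WT arrays, less than the 0.5 set as the bound. Low RNA input cannot be told apart all the same, because WT 1 is 1 array, was itself the lowest in WT and had a lower spike-in signal, 583 against 824. Of WT 2 and KO 8, the other arrays without Xist signal, 1 lay below the arrays of its group with Xist signal, KO 8 with 7.97, while WT 2 had the highest value in WT, 8.82, and an effect of sex cannot be told apart with 1 such array in WT. A different mixture of cells on KO 6 stays open and was not tested.

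Probe sets that the annotation ties to no gene or to several were outside the comparison of genes. Of 3564 such probe sets kept by the same filter, 589 passed the threshold, 246 lower and 343 higher in KO, with 29 lower and 22 higher by at least 2-fold.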

How the results depend on the processing

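The arrays WT 1 and KO 6 as a block or left out, the poly-A spike-in covariate and the Xist block were chosen after the data were seen, and the other settings before. No paired analysis was possible because the WT and KO arrays share no replicate numbers. The direction and call of Fezf2 held in every setting, and its log2 change ranged from -8.43 with an offset of 1 to -6.13 with an offset of 64. Counts moved by more than 1.5 times at an adjusted p threshold of 0.01, to 1314 lower and 1161 higher genes, and, for changes of at least 2-fold, with an offset of 64, to 70 lower and 97 higher genes, since a larger offset shrinks the fold of low signals. Lower genes made up 55.4% of the calls, and 50.7% with median centring. With WT 1 and KO 6 as a block 5094 genes were called, with the spike-in covariate 4405 and with the Xist block 3870, of which 4113, 4053 and 3744 were among those called without them.

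Aire ranged from -0.53 to -0.31 when 1 array was left out, with the call lost without WT 3, WT 4 or WT 5, and it kept its call at the 0.05 threshold in the other settings but not at 0.01 (adjusted p = 0.0282). With an estimated correlation the Fezf2-linked median of -1.72 (adjusted p = 0.22) and the Aire-dependent median of -0.27 (adjusted p = 0.50) no longer passed. The Aire-dependent list was also lost with array weights (-0.15, adjusted p = 0.069) and without WT 1 and KO 6 (-0.23, adjusted p = 0.053), and its median ranged from -0.40 to -0.14 when 1 array was left out. The mature mTEC median, never past the threshold, was 0.0043 with array weights, 0.033 without WT 1 and KO 6, and -0.05 without KO 6 alone. The cause was not tested. Of 110 named genes past the threshold, 10 lost their call in at least 1 of the 10 fits that left out 1 array, and none changed direction. Those genes were picked for large changes or small adjusted p. Of 236 genes past the threshold that were named or stood in a list or in a gene family that passed, 39 lost their call in at least 1 such fit. No quality value for low signals was used here, so changes of genes near the 40th percentile, 21.5 to 22.1 units, are the least certain.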

Other observations

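The scan of gene families, the comparison with Aire-dependent antigens and the test for one cornified cell type were chosen after the data were seen. So were the settings without WT 1 and KO 6, with the poly-A spike-in covariate or with Xist as a block.

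Gene families, grouped by the stem of their symbols, showed movements that the lists had covered only in part. Of 231 families with at least 8 measured members, 5 passed camera with a preset correlation, and none did with an estimated correlation (adjusted p = 0.99 for each). Of 18 kallikrein genes 10 were lower and none higher (median -0.47, adjusted p = 0.0024), led by Klk1b16 and with Klk1b1 at -1.14, Klk1 at -0.83 and Klk7, an epidermal protease, at -0.52. With quantile normalization or median centring 1 kallikrein gene was higher. The Klk1b genes are close paralogues, so their probe sets can share signal. Of 9 genes of the Sprr family, which encodes cornified envelope precursors, 6 were higher and none lower (median 0.71, adjusted p = 0.0024), and 1 was lower without WT 1 and KO 6 or with the Xist block. The higher ones included Sprr2j-ps, by its symbol a pseudogene, with 1.39. Sprr2d rose from 782 to 1756 and Sprr2f from 455 to 924. Of 9 fatty acid binding protein genes 6 were lower (median -0.94, adjusted p = 0.0024), with Fabp7 at -0.94 and Fabp12 at -0.98 beside the listed Fabp1, Fabp2 and Fabp9, while Fabp4 and Fabp5, at 8128 and 16893 in WT, had changes of 0.02 and -0.07.

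Of 8 genes of the Oas family, named for oligoadenylate synthetase, 5 were lower (median -0.55, adjusted p = 0.025), with Oas1f at -1.18 and Oas1h at -1.01. Oas1b, Oas2 and Oas3 had changes of -0.17, -0.41 and -0.003 that did not pass (limma, adjusted p = 0.12, 0.051 and 0.97). Oasl2, whose symbol has another stem, was outside this count and was higher. Its change was 0.40 to 0.60 in the fits that left out 1 array, and its call was lost in 5 of those 10. Of 35 collagen genes 15 were lower and 3 higher (median -0.13, adjusted p = 0.045). Col5a2 fell from 678 to 243 and Col14a1 from 835 to 357, while the basement membrane genes Col4a1 and Col4a2 were higher by 0.41 and 0.42. Keratin genes, with 22 of 45 lower and 7 higher, did not pass (adjusted p = 0.10). The direction of each of these families was the same with quantile normalization and median centring.

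The splits of the arrays argue against a chance division of these 10 arrays as the source of the changed genes. Of 100 of the 126 ways to split the 10 arrays into equal groups, 1, the real one, gave as many changed genes, 4113 against 1 in the highest other split, and the same 1 gave as many changed by at least 2-fold, 309 against 1. Every other split mixed WT and KO arrays, which widens the spread within its groups and lowers its count. Since the labels do not say that the arrays came from separate mice, a chance difference between a few mice or sorts is not excluded.

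The fall of the enterocyte and hepatocyte list may reflect a programme that depends on Fezf2. Its median was -1.01 without WT 1 and KO 6, so the fall did not rest on these arrays. With the poly-A spike-in level of all arrays as a covariate the median was also -1.01, with 22 members lower and none higher. These values argue against RNA input, as far as the spike-in signal measures it, as the source of the fall. With the Xist block the median was -1.02, with 22 of 24 members lower and none higher. These values argue against the unequal sex of the groups as the source of the fall. Whether the size of the fall differs between the sexes cannot be told, because only 1 WT array lacked Xist signal. The list median with all arrays lay below the median of -0.21 of 15 Aire-dependent antigens outside the liver and intestine lists (two-sided permutation p = 0.00024, 100000 resamples). Aire-dependent antigens that also stand in those lists were left out, among them Fabp2 (-1.64) and Fgb (-1.15), which fell further than the list median. The median of all 19 Aire-dependent antigens was -0.27. The permutation was over genes, which are not independent replicates. With such a choice of antigens its p-value cannot decide whether the list differs from Aire-dependent antigens. The lower Aire level cannot be told apart, because the 15 antigens varied (SD 0.496 of the log2 changes). Of the 15, 1, Sult1c2, fell by at least as much as the list median, as did Fabp2 and Fgb among those left out. Whether each cell lost these transcripts or a subset of cells with an enterocyte or hepatocyte programme became rarer stays open in sorted bulk cells.

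The opposite movement of Krt1 and Krt10 and of other cornified genes may be a change within the cornification programme. A changed share of one cornified cell type that carries all members would, by itself, move them one way. Of the members that kept their call in all 10 fits that left out 1 array, 2 (Krt1 and Krt10) were lower and 8 higher. These counts restate the pattern that prompted the test, and they argue only against such a share as the sole change. All 4 of Krt1, Krt10, Sprr1a and Sbsn kept their direction and call without WT 1 and KO 6. So did 12 of all 13 members past the threshold, and the pattern thus did not rest on these arrays. They are 1 array of each group, so leaving them out cannot by itself decide whether RNA input played a part. With the poly-A spike-in level as a covariate, 11 members were higher and 3 lower. A probe set that reads another transcript cannot be told apart from the gene here, because 0 further probe sets of Krt1 and Krt10 were kept. A shift between cornified states that carry different members stays open and was not tested.

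Genes next to Fezf2 on chromosome 14 might carry passenger DNA of the targeted locus, since the strain of the targeted cells is not given in the labels. Among up to 50 measured genes on each side of Fezf2, 67 in all, 25 were changed (37.3%), against 29.2% of the other genes (one-sided Fisher exact p = 0.0936). Only 1 of the 67 changed by at least 2-fold, against 2.19% of all genes. The share was higher but not past the threshold, and passenger DNA cannot be told apart from the effect of Fezf2 with this test.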
